A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

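The series measured trimethylation of histone H3 at lysine 4 (H3K4me3), a mark that lies at the 5 prime ends of transcribed genes in yeast, by CUT&RUN, in which an antibody directs a nuclease to cut out the chromatin it binds. The cells were the budding yeast strain BY4741, a haploid of mating type a. Each strain carried a synthetic copy of the human HPRT1 locus or of its reversed form, HPRT1R. The synthetic DNA was present either on a yeast artificial chromosome (YAC) or integrated into chromosome XI. Of the 16 samples, 8 were H3K4me3 libraries in 4 groups of 2, and 8 were IgG control samples, which were not analysed here. Per the labels' protocols, YAC strains grew in a synthetic medium without leucine (SC-Leu) and integrated strains in the rich medium YPD, at 30 °C, so that configuration and medium always changed together. Cultures were diluted to an optical density of 0.1, grown for 6 hours to about 0.6, and processed with 0.5 µg of antibody.

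Each H3K4me3 library came with 1 list of peaks, which the authors had called per sample as far as the labels tell. Per the submitters' processing notes, the tools were bcl2fastq 2.20, Bowtie2 2.2.9, SAMtools 1.9, deepTools 3.5.0 and MACS2 2.1.0, with the sacCer3 build. The settings of the caller, the minimum mapping quality and whether the IgG samples served as its control are not given in the sources used here. Besides the native chromosomes, the lists hold 1 further contig per sequence, which by its name is the synthetic insert within its vector. For each peak the authors deposited a fold over the caller's expectation (a ratio), a p-value and a q-value as −log10, a score derived from the q-value, and the offset of the summit. These are the authors' own values. They were used only to describe, rank or filter peaks within 1 list.

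Groups were taken from the sample titles, which name the assay ChIP rather than CUT&RUN. For HPRT1 YAC replicate 2, the cell line entry of the labels names the HPRT1R YAC, while its title, source name and genotype name HPRT1. Its peaks lie on the HPRT1 contig, and it was kept in the HPRT1 YAC group. The file of HPRT1R YAC replicate 1 is named by another pattern than the other 7. Nothing in the labels says that replicates came from separate cultures, so that the p-values measure the spread between these samples, which may be technical.

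The lists hold 30753 peaks in all, and 0 intervals were repeated within a list. Read totals cannot be read from peak lists. They do hold the local read depth, however. Since the caller's fold is the observed over the expected pileup (each plus a pseudocount of 1) and its p-value is a Poisson tail, the whole-number pileup at each summit and the caller's expected pileup were solved for from both. At least 99.3% of the peaks of each library were matched within 0.001 in −log10 p, and peaks off by 0.01 or more were left out of these values. The expected pileup had a lower limit in every library, shared by 51.4 to 66.6% of native peaks and taken as the 10th percentile over native peaks and called the genome-wide expected pileup. It lay between 76.2 and 98.9 reads, and pileups of this size set the counting error of a fold. Where libraries have no peak, the depth is unknown.

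Native values are over the 16 nuclear chromosomes. Their lengths were taken as the end of the last annotated gene or peak, 12053405 bp in all. The contig was taken to run to the end of its last peak, 113928 bp for HPRT1 and 113922 bp for HPRT1R. The integrated libraries had no peak past 99495 bp on HPRT1 and 98008 bp on HPRT1R, and values over the first 100 kb are given beside those over the contig. For simplicity the first 100 kb is called the insert, although the exact border between insert and vector was not given. Genes came from the RefSeq table of assembly R64, which is the assembly that sacCer3 names, with the strand read from the systematic names. The match of the coordinates was checked on the data: 42.8% ± 5.10 (SD, n = 8) of genes had a summit within the 500 bp after the gene start, against 15.1% ± 0.850 (SD, n = 8) when gene starts were shifted by 2000 bp. A gene counted as marked when a peak overlapped by at least 1 bp the window from 200 bp upstream to 500 bp downstream of its annotated start. Overlap between lists needed 1 bp.

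Synthetic and native values of the same library were compared with an exact two-sided sign-flip permutation test over 8 libraries, and YAC with integrated or HPRT1R with HPRT1 libraries with an exact two-sided permutation test of means, 4 against 4. The smallest p that these can give is 0.00781 and 0.0286. Benjamini-Hochberg adjustment was over the 6 tests of density and coverage. Intervals of differences are 95% intervals from inverting the exact test. Shared positions were tested against 10000 circular shifts, and gene lists against 10000 random lists of the same size. The tests, 19 gene lists, alternatives and the rule for named genes were fixed before the data were examined. All listed symbols were found in the gene table. The rule named, for each contrast, up to 15 genes per direction marked in 4 of 4 libraries of one side and 0 of the other, and the 10 genes with the highest mean percentile of fold. In each list it named the top 2 members marked in all 8 libraries and the first 2 in alphabetical order among those marked least, or every member in lists of 8 or fewer, and on the contigs the 5 strongest peaks found in both configurations and those found in both replicates of 1 configuration. Of the genes so chosen, 1 is not reported here. Alternatives were a −log10 q of at least 5, equal numbers of peaks (the 3463 of the shortest list), each library left out, other overlap rules, other gene windows, a contig length of 100 kb, and permutation within strata or with the replicate number as a block. Comparing the expected pileup, comparing peak strength between the sequences and restricting further results to 100 kb or to integrated libraries were chosen after seeing the data.

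Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. The code was tested on simulated data. In lists simulated for the YAC and integrated groups over 6002 genes, 100% of the planted genes whose windows touch no other gene's were recovered and 0 genes were called in error, and the exact pileup was found for 100% of 4000 simulated peaks.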

Results

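H3K4me3 peak lists of 8 yeast libraries were examined: HPRT1 on a YAC, HPRT1 integrated on chromosome XI, HPRT1R on a YAC and HPRT1R integrated, with 2 libraries in each group. The purpose given for the series was to learn whether the synthetic sequences are active in yeast and how they compare with the rest of the genome. The lists held 3463 to 4049 peaks, with a mean of 3844 ± 202 (SD, n = 8). HPRT1 YAC libraries had 4049 and 3964 peaks, HPRT1 integrated libraries 3794 and 3642, HPRT1R YAC libraries 3463 and 3939, and HPRT1R integrated libraries 4021 and 3881. Native peaks had a median width of 540 to 699 bp and a median fold of 1.86 to 2.36, the fold being the authors' own value. The genome-wide expected pileup, the measure of depth that could be recovered, was 85.4 and 92.7 reads in the HPRT1 YAC libraries, 76.2 and 76.5 in the HPRT1 integrated, 98.9 and 78.6 in the HPRT1R YAC, and 78.0 and 83.3 in the HPRT1R integrated libraries.

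Native peaks overlapped about as much between groups as within them. Peaks covered 22.8 to 26.0% of native bases. Within groups, 93.9% ± 2.38 (SD over 8 ordered pairs) of native peaks overlapped a peak of the other replicate. Between libraries that shared only the configuration the share was 93.4% ± 2.32 (SD over 16 ordered pairs), between those that shared only the sequence 92.5% ± 2.64 (SD over 16 ordered pairs), and between those that shared neither 93.1% ± 2.36 (SD over 16 ordered pairs). With a reciprocal overlap of 50%, the share was 80.9% ± 6.41 within groups (SD over 8 ordered pairs), and 78.4% ± 7.50, 76.1% ± 7.31 and 79.6% ± 2.92 in the same order between them (SD over 16 ordered pairs each), a comparison chosen after seeing the data. With either rule the means differed by less than their largest spread, so that differences at single places are not excluded. On the synthetic contig 85.3 to 96.0% of peaks overlapped one of the replicate. In HPRT1 YAC replicate 2, whose labels conflict, 88.9% of the 63 contig peaks overlapped a contig peak of HPRT1 YAC replicate 1.

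In the H3K4me3 libraries both synthetic sequences carried called peaks along the insert, more densely than native chromosomes. A called peak does not by itself show the mark. Each list also held 15 to 37 peaks on the mitochondrial genome, which carries no histones. The IgG samples were not analysed here, so that background over the insert was not measured. The contig held 4.88 ± 0.675 peaks per 10 kb (SD, n = 8), against 3.12 ± 0.167 (SD, n = 8) on native chromosomes of the same libraries, a ratio of 1.56. Peaks covered 36.4% ± 9.55 (SD, n = 8) of the contig and 24.3% ± 1.18 (SD, n = 8) of native bases. In the integrated libraries, 31.3% ± 0.532 (SD, n = 4) of the insert lay under peaks, against 25.1% ± 0.841 (SD, n = 4) of native bases. Over the whole contig, whose last stretch had no peak in these libraries, the value was 27.5% ± 0.466 (SD, n = 4). In the YAC libraries 43.7% ± 1.48 (SD, n = 4) of the insert and 23.4% ± 0.698 (SD, n = 4) of native bases lay under peaks. Density and coverage were higher on the contig in 8 of 8 libraries (exact sign-flip permutation test, two-sided, p = 0.00781 for each, the smallest possible; adjusted p = 0.0234, n = 8). These libraries measure the same contigs again, and YAC and integrated libraries enter together. The p-value therefore speaks to how repeatable the difference was, not to synthetic DNA in general. With the 4 integrated libraries alone the exact test cannot go below 0.125, which it reached, with the insert higher by 6.19 percentage points and by 1.9 peaks per 10 kb in 4 of 4 libraries.

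**Figure D1:**
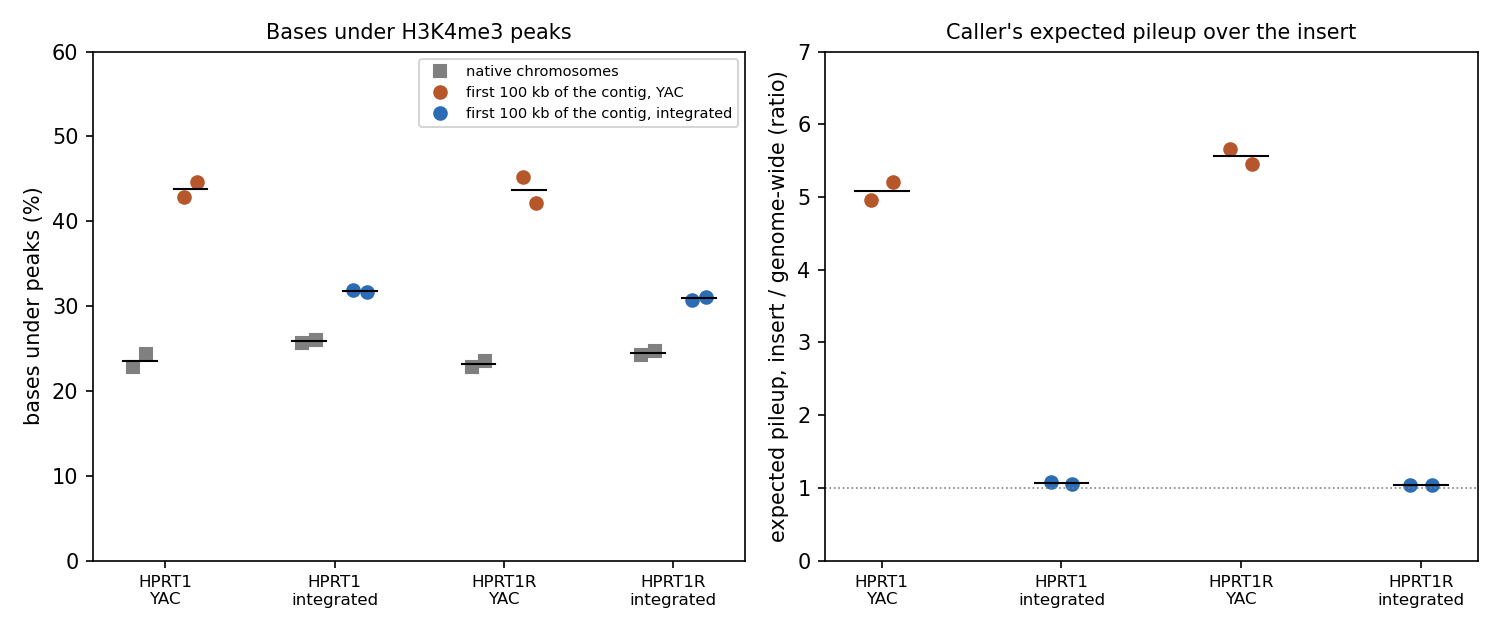
Left, percent of bases under H3K4me3 peaks on native chromosomes (grey squares) and on the first 100 kb of the synthetic contig (circles) for each of the 4 groups; each point is 1 library and the black line is the mean of 2. Right, the caller's expected pileup over the insert divided by the genome-wide value (median over insert peaks, 1 point per library), which was 4.96 to 5.66 in YAC libraries and 1.04 to 1.08 in integrated ones.

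Set among native windows of the same length, the contig stood at percentile 99.6 or above in number of peaks in every library. In coverage it stood at percentile 100 in the 4 YAC libraries, whereas the integrated libraries placed it between the percentiles 51.5 and 66.6. Over the insert alone, compared with 9821 native windows of 100 kb that stay 20 kb from the chromosome ends, the integrated libraries lay between the percentiles 87.8 and 95.3 in coverage. Insert peaks had lower folds than native ones: their median fold was 1.48 to 1.87, against 1.86 to 2.36 for native peaks. In YAC libraries, insert folds are over an expectation 4.96 to 5.66 times the genome-wide value, so that the baselines are unlike there. In integrated libraries, where this ratio was 1.04 to 1.08, the medians were 1.77 to 1.87 on the insert and 2.16 to 2.36 on native chromosomes. The median contig peak stood at percentile 22.6 ± 8.70 (SD, n = 8) of the native peaks of its own library by fold. The strongest insert peak of any library had a fold of 3.25. Native maxima ranged from 11.7 to 14.6, all from the peak of YLR162W and RRT15 beside the ribosomal DNA, whose value is uncertain; the next strongest gene peak, at HBS1, had a mean fold of 4.64.

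The same stretches were marked in both configurations for a large part of each sequence. On HPRT1, 38 regions had peaks in both replicates of both configurations, and the 5 strongest lay at positions 55474 to 57025, 75825 to 78423, 3876 to 5781, 49846 to 51600 and 97571 to 99495 of the contig, at mean percentiles of 83.5, 78.0, 74.8, 71.2 and 62.7 among native peaks. On HPRT1R there were 32 such regions, the 5 strongest at 95817 to 97043, 56629 to 58341, 110 to 5063, 16046 to 18107 and 62153 to 64348, at mean percentiles of 76.5, 72.2, 71.4, 61.7 and 56.8. Regions are unions of overlapping peaks of the libraries, so that a single library may have marked only part of one. Of the 55 HPRT1 regions found in both YAC replicates, 39 (70.9%) overlapped a region of both integrated replicates, where circular shifts gave 55.3% (permutation p = 0.0117, one-sided). For HPRT1R it was 32 of 43 (74.4%), against 57.5% by chance (permutation p = 0.0025, one-sided). These shifts cover the stretch past 100 kb, where integrated libraries had no peak. Over the first 100 kb alone, HPRT1 had 75.0% against 61.7% by chance (permutation p = 0.0171, one-sided). HPRT1R had 82.1% against 64.1% there (permutation p = 0.0113, one-sided). With equal numbers of peaks per library, the HPRT1R share was 58.1% and passed the threshold no longer (permutation p = 0.158). No gene annotation of the synthetic contigs was used here, so that these regions have positions but no named features.

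**Figure D2:**
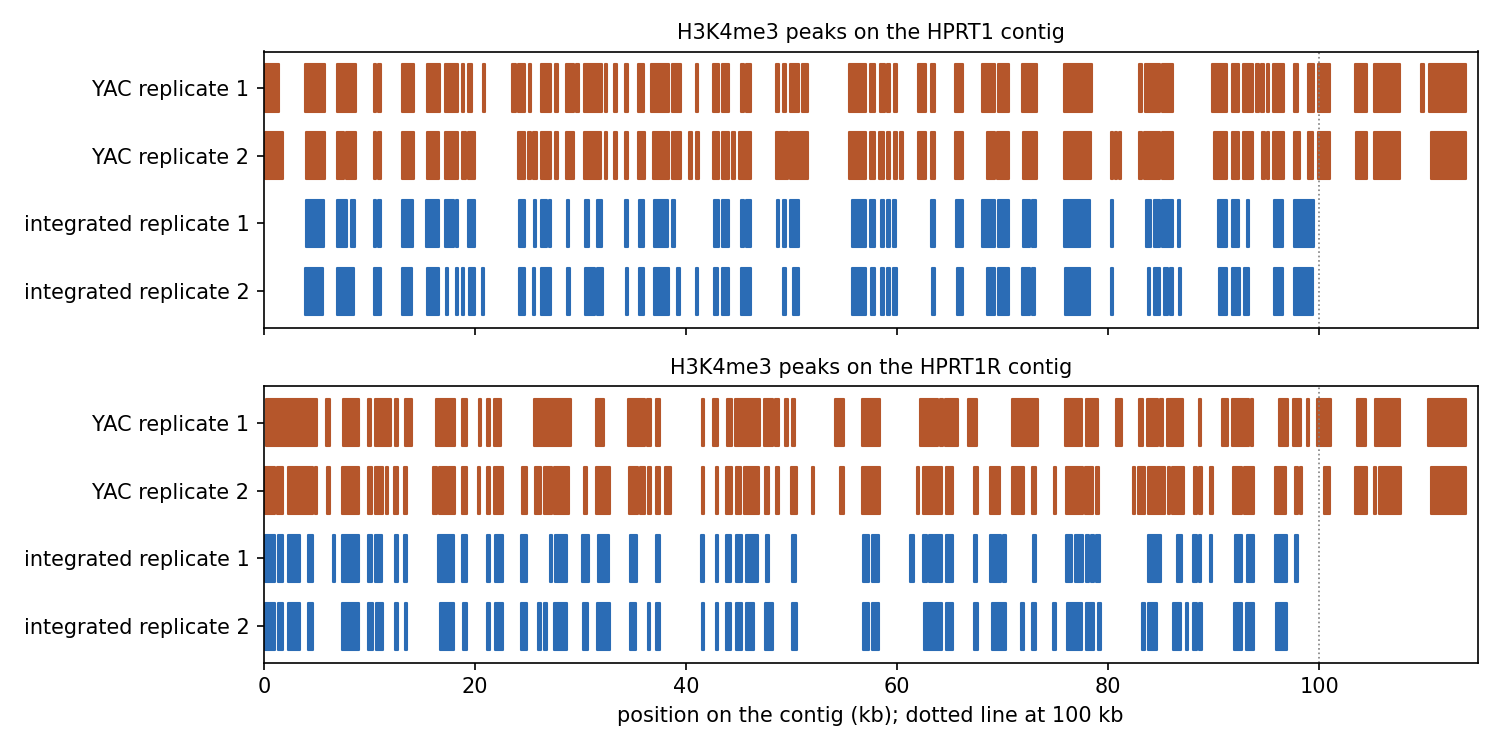
H3K4me3 peaks along the HPRT1 contig (top) and the HPRT1R contig (bottom), with the position in kb on the x axis and 1 row per library; bars are peaks drawn to scale, YAC libraries in brown and integrated libraries in blue. Integrated libraries have no peak past 100 kb, where each YAC library has 3 to 5.

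YAC libraries had more of the synthetic sequence under peaks than integrated ones. Coverage of the contig was 45.3% ± 1.52 (SD, n = 4) against 27.5% ± 0.466 (SD, n = 4), and that of the insert 43.7% ± 1.48 (SD, n = 4) against 31.3% ± 0.532 (SD, n = 4). The reads were also more abundant there: the expected pileup over the insert was 5.32 ± 0.307 (SD, n = 4) times the genome-wide value in YAC libraries and 1.05 ± 0.0187 (SD, n = 4) times in integrated ones. Regions found in both YAC replicates and absent from integrated libraries included 3 beyond 100 kb on each contig, at 103420 to 104520, 105205 to 107663 and 110423 to 113928 on HPRT1 and at almost the same positions on HPRT1R (103430 to 104497, 105207 to 107720 and 110295 to 113922), with mean percentiles from 69.0 to 89.1. A further such region spanned the 100 kb point, from 99887 to 101033 on HPRT1 (mean percentile 78.5) and from 99759 to 101076 on HPRT1R (mean percentile 87.8). On HPRT1 the stretch from 62 to 1841 was also marked in YAC libraries alone (mean percentile 53.5). The other such regions of the insert, 8 on HPRT1 and 4 on HPRT1R, had mean percentiles of at most 8.69, and 1 region, at 86600 to 86884 of HPRT1, was found in both integrated replicates alone (mean percentile 3.29).

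The coverage difference on the insert was 12.4 percentage points (95% interval 10.2 to 14.6) and that on the contig 17.8 points (95% interval 15.3 to 19.8), higher in 4 of 4 YAC libraries than in any integrated one. Each had p = 0.0286 by the exact permutation test (two-sided, n = 4 and 4), the smallest possible, and an adjusted p of 0.0571 over 6 tests, so that neither passed the correction. On the contig, the exact permutation p within sequences was 0.0556, again the smallest possible. Whether integrated strains carry the stretch past 100 kb is not known here; if it is vector that they lack, part of each contig difference was fixed by the strains. Peak density on the insert was 5.72 ± 0.704 per 10 kb in YAC and 5.03 ± 0.126 in integrated libraries, a difference of 0.7 (SD, n = 4 each; exact permutation p = 0.143, adjusted p = 0.214). On the contig it was 5.35 ± 0.676 per 10 kb in YAC and 4.41 ± 0.111 in integrated libraries (SD, n = 4 each; exact permutation p = 0.0857, adjusted p = 0.129). The call for contig density rests on HPRT1R YAC replicate 1, which had the fewest peaks of all libraries: without it the difference was 1.27 per 10 kb (exact permutation p = 0.0286). It also passed with a −log10 q of at least 5 (1.49 per 10 kb, exact permutation p = 0.0286). Configuration and medium cannot be separated here. Native coverage ran the other way, at 23.4% ± 0.698 in YAC and 25.1% ± 0.841 in integrated libraries (SD, n = 4 each; exact permutation p = 0.0571).

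HPRT1R and HPRT1 could not be told from each other in the density or coverage of H3K4me3 peaks, while the strength of their peaks ran in opposite directions in the 2 configurations without passing the test. By fold, the median contig peak of the YAC libraries stood at percentile 33.1 ± 5.37 of native peaks for HPRT1 and 12.7 ± 2.38 for HPRT1R (SD, n = 2 each). In the integrated libraries it stood at 19.0 ± 0.893 for HPRT1 and 25.6 ± 5.85 for HPRT1R (SD, n = 2 each). The baselines of the configurations are unlike: the expected pileup over the insert was 4.96 to 5.66 times the genome-wide value in YAC libraries. In integrated ones it was 1.04 to 1.08 times. The YAC values also include peaks past 100 kb, where integrated libraries had none. The difference of differences was -27.0 percentiles, with the smallest p that the exact permutation within sequences can give (p = 0.0556, two-sided), and over both configurations HPRT1R differed from HPRT1 by -6.91 (exact permutation p = 0.314, two-sided). The permutation within sequences exchanges configurations, so that it asks for any YAC-integrated difference and not for the dependence on the sequence alone. These strength tests were chosen after seeing the data. The HPRT1R contig held 4.83 ± 0.765 and the HPRT1 contig 4.94 ± 0.685 peaks per 10 kb (SD, n = 4 each), a difference of -0.109 with a 95% interval from -1.14 to 1.66 (exact permutation p = 1, two-sided). Coverage was 36.1% ± 10.4 and 36.7% ± 10.2 (SD, n = 4 each), a difference of -0.663 percentage points with a 95% interval from -19.2 to 18.9 (exact permutation p = 0.743, two-sided). Both intervals are wide, as YAC and integrated libraries enter together. They hold the spread between configurations and do not bound the difference within a configuration. Permuted within configurations, the coverage difference had p = 0.5 (exact permutation test, two-sided). The sign of either difference changed with the library left out. Leaving 1 out makes the share of YAC libraries unequal between the sequences, so that the YAC-integrated difference enters. The changes in coverage therefore do not show that the comparison rests on single libraries. The density difference was 0.088 without HPRT1 YAC replicate 1 or 2 and 0.0368 without HPRT1R YAC replicate 1 or HPRT1R integrated replicate 2. The coverage difference was 2.09 and 2.47 without HPRT1 YAC replicates 1 and 2, and 2.38 and 2.25 without HPRT1R integrated replicates 1 and 2. By group, the insert was under peaks for 43.8% ± 1.25 in HPRT1 YAC, 43.7% ± 2.24 in HPRT1R YAC, 31.8% ± 0.133 in HPRT1 integrated and 30.9% ± 0.301 in HPRT1R integrated libraries (SD, n = 2 each). Whether the YAC-integrated difference in density depended on the sequence could not be decided. The difference of differences was -0.483 per 10 kb (exact permutation within sequences, p = 0.944, smallest possible p = 0.0556), and 0.307 without HPRT1R YAC replicate 1. A YAC-integrated difference common to both sequences widens the spread of this permutation. A high p therefore does not show that the sequence plays no part.

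By the rule of 1 bp overlap, most native protein-coding genes were marked at the 5 prime end. Of 6002 genes, 77.5% ± 1.68 (SD, n = 8) had a peak there per library. The share that this wide rule would give by chance was not determined. By a summit within 500 bp after the gene start the share was 42.8% ± 5.10 (SD, n = 8). With gene starts shifted by 2000 bp that share was 15.1% ± 0.850 (SD, n = 8). Of these genes, 3991 (66.5%) were marked in all 8 libraries and 887 (14.8%) in none. The strongest mark belonged to YLR162W and RRT15, 2 small open reading frames on chromosome XII beside the ribosomal DNA, with a fold of 13.0 ± 0.853 (SD, n = 8). Their peak is shared, and reads from the repeated ribosomal DNA may be split between copies, so that this value is uncertain. Among genes marked in all 8 libraries, next came the neighbours HBS1, MRPL20 and PRP16 on chromosome XI (fold 4.64 ± 0.587), SSL2 and CCT2 on chromosome IX (fold 4.61 ± 0.660), EMG1 and SKG3 on chromosome XII (fold 4.45 ± 0.563) and PSR1 on chromosome XII (fold 4.57 ± 0.840; SD, n = 8 each), where neighbours share 1 peak. They work in ribosome rescue, the mitochondrial ribosome, splicing, transcription and DNA repair, protein folding and ribosome assembly, among others.

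Genes of ribosomal proteins, of purine synthesis and of amino acid synthesis other than leucine, isoleucine, valine and methionine were marked more often than random lists. Of 137 ribosomal protein genes, 133 (97.1%) were marked in all 8 libraries, among them RPS24B (fold 4.44 ± 0.798; SD, n = 8) and RPL4B (fold 4.49 ± 0.692; SD, n = 8). RPL18B was marked in 5 (two-sided permutation test against random lists of protein-coding genes, adjusted p = 0.000543 over 19 lists, the smallest reached). All 13 purine synthesis genes were marked in 8 libraries, with ADE8 and ADE6 at folds of 3.14 ± 0.325 and 3.11 ± 0.320 and ADE12 lower, at 1.78 ± 0.217 (SD, n = 8 each; permutation adjusted p = 0.0218). Of 43 genes for other amino acids, 40 were marked in all, led by THR1 (fold 4.35 ± 0.500; SD, n = 8) and TRP1 (fold 3.88 ± 0.627; SD, n = 8), while ARO7 was marked in 1 library (permutation adjusted p = 0.000543). In leucine, isoleucine and valine synthesis 11 of 13 genes were marked in all, LEU4 and BAT1 strongest at folds of 3.24 ± 0.227 and 3.15 ± 0.397 (SD, n = 8 each; permutation adjusted p = 0.34). The ribosomal protein result depends on how a gene is called marked: by a summit within 500 bp after the gene start, the share differed from that of random lists by -6.06 percentage points (permutation adjusted p = 0.19), and the purine call also ended (permutation adjusted p = 0.585), as it did with a −log10 q of at least 5 (permutation adjusted p = 0.0563).

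Meiosis, galactose, seripauperin, COS, subtelomeric and tRNA genes were marked less often than random lists. Of 46 meiosis and sporulation genes, 0 were marked in all libraries and 44 in none, AMA1 and DIT1 among the latter (permutation adjusted p = 0.000543). Of 7 galactose genes only GAL80, which encodes the repressor of the pathway, was marked, in all 8 libraries (fold 2.74 ± 0.237; SD, n = 8), whereas GAL1, GAL2, GAL3, GAL4, GAL7 and GAL10 were marked in 0 (permutation adjusted p = 0.0308). The galactose call was lost with a −log10 q of at least 5, equal numbers of peaks, peaks over the gene body and summits (permutation adjusted p = 0.0563, 0.073, 0.182 and 0.727). None of 24 seripauperin genes, such as PAU1 and PAU10, and none of 12 COS genes, such as COS1 and COS10, was marked in any library (permutation adjusted p = 0.000543 for each; by summits permutation adjusted p = 0.0988 and 0.535). Of 240 genes within 20 kb of a chromosome end, which include members of both families, 22 (9.17%) were marked in all and 183 in none (permutation adjusted p = 0.000543). YHR214C-B and YHR214C-C were marked in 8 libraries and AAD10 and AAD15 in 0. Members of such families are near-identical copies, so that a lack of peaks may also reflect how the authors treated reads with several matches. Of 275 tRNA genes, 45 (16.4%) were marked in all, with YNCG0037W and YNCG0020C strongest at folds of 3.72 ± 0.610 and 3.54 ± 0.429 (SD, n = 8 each), and EMT1 and EMT2 in 0 libraries (permutation adjusted p = 0.000543).

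**Figure D3:**
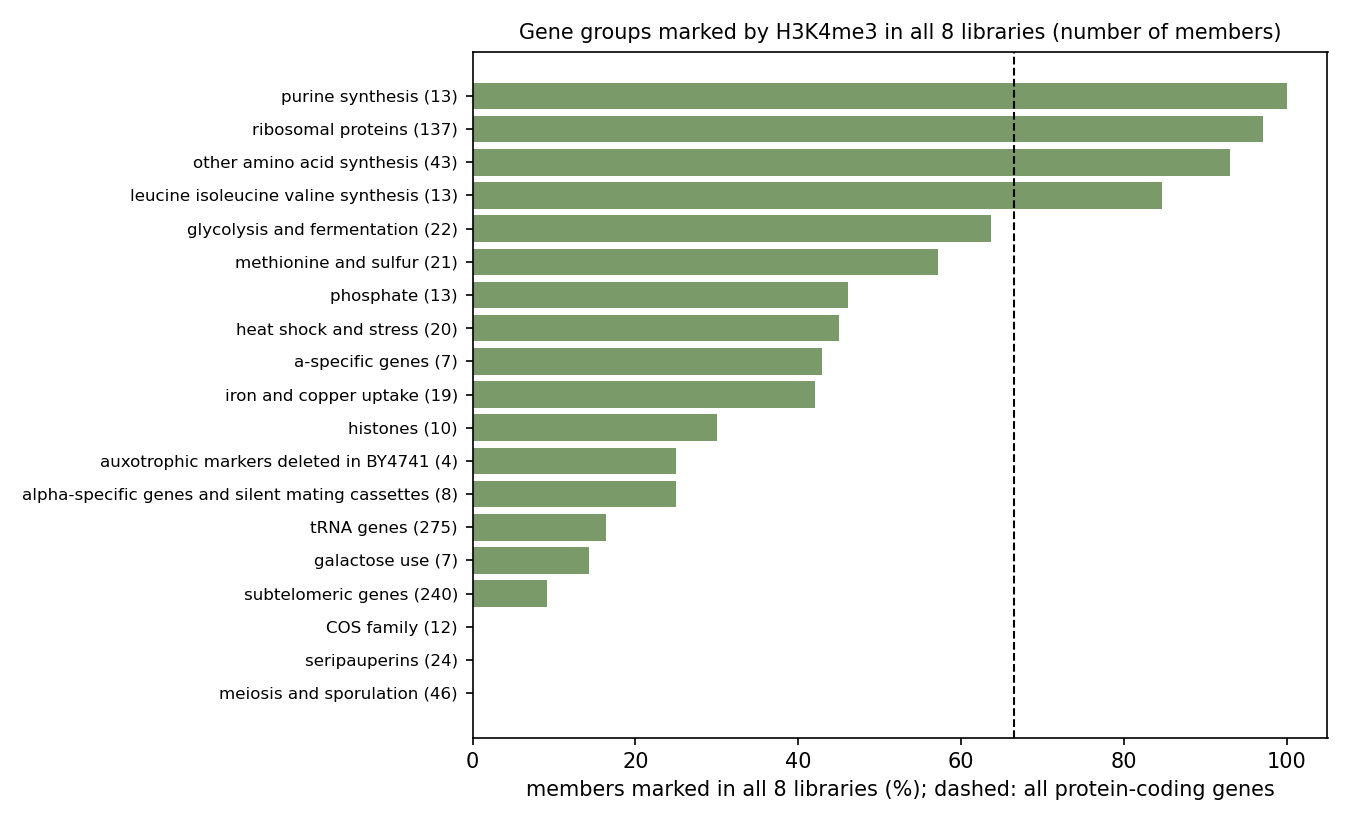
Percent of the members of each of the 19 gene groups with a 5 prime H3K4me3 peak in all 8 libraries (bars; number of members in brackets); the dashed line marks the 66.5% of all protein-coding genes. Purine synthesis reaches 100% and meiosis and sporulation 0%.

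The other groups did not differ detectably from random lists of their size. Histone genes were marked in all libraries in 3 of 10 cases (permutation adjusted p = 0.0801), with HHO1 and HHT2 at folds of 3.04 ± 0.365 and 2.69 ± 0.332 (SD, n = 8 each) and HHF1 and HHT1 in 1 library. Glycolysis and fermentation genes were marked in 14 of 22 cases (permutation adjusted p = 0.941); their share differed from random lists by -2.79 percentage points, and by 3.95 without HPRT1R YAC replicate 1. PFK2 and PGK1 stood at folds of 3.05 ± 0.425 and 2.87 ± 0.387 (SD, n = 8 each), and ADH2 and HXK1 were marked in 0 libraries. Of 21 methionine and sulfur genes 12 were marked in all (permutation adjusted p = 0.518), with MET16 at 3.74 ± 0.472 and MET28 at 2.82 ± 0.430 (SD, n = 8 each), and MET17 and MET3 in 0 libraries. Of 13 phosphate genes 6 were marked (permutation adjusted p = 0.282), PHO8 and VTC4 strongest at 3.77 ± 0.553 and 2.86 ± 0.409 (SD, n = 8 each), and PHM6 and PHO11 in 0 libraries. Iron and copper uptake had 8 of 19 (permutation adjusted p = 0.0801), with TIS11 at 3.64 ± 0.623 and FET3 at 3.21 ± 0.448 (SD, n = 8 each), and FIT1 and FIT2 in 0 libraries. Without HPRT1R YAC replicate 1, the histone and the iron and copper lists passed the threshold (permutation adjusted p = 0.044 for each), as did the list of alpha-specific genes and silent cassettes. Heat shock and stress genes had 9 of 20 (permutation adjusted p = 0.113), with TPS1 at 2.90 ± 0.293 and YDJ1 at 2.61 ± 0.214 (SD, n = 8 each), and DDR2 and HSP12 in 0 libraries.

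Genes that report the genotype were examined one by one. BY4741 carries deletions at 4 auxotrophic markers. URA3 and MET17 were marked in 0 libraries, LEU2 in the 4 YAC libraries, and HIS3, of which BY4741 lacks only an internal part, in 8 (fold 2.91 ± 0.187; SD, n = 8). The list gave a permutation adjusted p of 0.282. Among genes specific to mating type a, BAR1, STE6 and STE2 were marked in 8 libraries (folds 3.16 ± 0.385, 2.58 ± 0.308 and 2.48 ± 0.377; SD, n = 8 each), ASG7 in 3, MFA1 in 2, MFA2 in 1 and AGA2 in 0 (permutation adjusted p = 0.38). Among genes of mating type alpha and the silent cassettes, MF(ALPHA)1, MF(ALPHA)2, SAG1, HMLALPHA1 and HMLALPHA2 were marked in 0 libraries and STE3 in 1 (permutation adjusted p = 0.0722). This list passed the threshold with a −log10 q of at least 5 (permutation adjusted p = 0.00489), with equal numbers of peaks (permutation adjusted p = 0.00427) and with peaks over the gene body (permutation adjusted p = 0.0148), and not with summits (permutation adjusted p = 0.727). HMRA1 and HMRA2 were marked in 8 (fold 1.94 ± 0.329; SD, n = 8), but the cassette shares its sequence with the mating type locus of these a cells, so that its reads cannot be assigned to one of them.

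Between YAC and integrated strains, few native genes differed in being marked. LEU2, which encodes the leucine synthesis enzyme needed in medium without leucine, was marked in 4 of 4 YAC and 0 of 4 integrated libraries at chromosome III, 91324 to 92418, with a fold of 4.56 ± 0.663 and a percentile of 99.9 ± 0.0369 (SD, n = 4). The strain lacks the native gene, and medium without leucine selects for a LEU2 copy. The expected pileup there was 1.01 times the genome-wide value, and the mean pileup was 410 reads. Over the insert of the same libraries the expected pileup was 5.32 times the genome-wide value. Where the reads at LEU2 arose was not tested, so that its fold may not measure the strength of a mark. The other 8 genes on the YAC side were HMX1 (heme oxygenase), SUL2 (sulfate uptake), CYC1 (cytochrome c), COX12 (a cytochrome oxidase subunit), COA2 (cytochrome oxidase assembly), COT1 (metal transport into the vacuole), ATG33 (mitophagy) and YLR326W, at mean percentiles from 8.75 to 70.4. On the integrated side were 18 genes, led by CHA1, which breaks down serine and threonine, at chromosome III, 15798 to 16880 (fold 3.58 ± 0.249, percentile 94.4 ± 0.883; SD, n = 4). Next came AHC2 (percentile 44.7), CRR1 (percentile 37.3), VPS53 (percentile 34.9), UBC12 (percentile 30.7), ATF1, an alcohol acetyltransferase (percentile 30.6), and TOM1 (percentile 23.2), then ROG1, YOL014W, MST27, YDL242W, TPO2, ERV14 and EUG1 at percentiles from 12.5 to 17.6.

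Which genes were separated depended on the setting. Of the 9 genes on the YAC side and the 18 on the integrated side, 5 and 6 were separated with equal numbers of peaks, 5 and 10 with a −log10 q of at least 5, 5 and 15 with peaks over the gene body, and 3 and 5 with summits. For 4 of these 27 genes, CHA1, HMX1, SUL2 and COA2, the peak that marked the gene overlapped a peak in 4 of 4 libraries of the other side, which ended short of the window. For 19 genes no library of the other side had a peak there. ERG26, PTC4 and MAS1, also on the integrated side, fall outside the naming rule and lay at percentiles of 9.45, 6.56 and 5.97. On the YAC side the count was 14 without HPRT1R YAC replicate 2, where the rule asks for fewer libraries and is easier to meet. Fisher's exact test gave 27 genes at p = 0.0286, the smallest possible with 4 and 4 libraries, and 0 of 6002 genes after Benjamini-Hochberg adjustment, which 27 genes at this p cannot pass. Of the 19 gene lists, 0 differed between YAC and integrated libraries after adjustment, which the design makes hard to reach, since a single list at the smallest possible p adjusts to 0.543. The smallest exact permutation p was 0.0286 for the auxotrophic markers (adjusted p = 0.543), through LEU2. The tRNA genes had 29.4% ± 2.00 marked in YAC and 35.9% ± 3.19 in integrated libraries (SD, n = 4 each; exact permutation p = 0.0571, adjusted p = 0.543).

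No native gene separated the sequences: 0 genes were marked in 4 of 4 HPRT1 and 0 of 4 HPRT1R libraries, and 0 the other way. Leaving out a library relaxes this rule, so that the count can only stay or rise. It was 7 genes without HPRT1 YAC replicate 1, 5 without HPRT1R YAC replicate 2 and 4 without HPRT1R integrated replicate 1. It was 2 without HPRT1R YAC replicate 1 and 1 without HPRT1 integrated replicate 2. On chromosome XI, which carries the integrated copies, 3 stretches of at least 100 bp were under a peak in 4 of 4 libraries of one configuration and in none of the other, all on the integrated side, at 145961 to 146174, 356573 to 356812 and 454724 to 455038. This made 4.52 per Mb, against 6.67 per Mb on the other chromosomes, where 76 such stretches lay, 15 on the YAC side and 61 on the integrated side. With a library left out the rule for such stretches is easier to meet. The number on chromosome XI was then 7 without HPRT1R integrated replicate 1, 6 without HPRT1R YAC replicate 2 and 5 without HPRT1R integrated replicate 2. The position of the integration was not known here.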

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

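The outlier measures and the comparisons of mitochondrial peaks and of peak strength were chosen after a look at the lists. Peaks on the mitochondrial genome, which carries no histones, entered no comparison of the report. Their number averaged 30.8 in YAC libraries (range 23 to 37) and 18 in integrated libraries (range 15 to 20), and differed by the exact permutation test (two-sided, p = 0.0286, the smallest possible, n = 4 and 4). The strength of contig peaks differed between the sequences in opposite directions: HPRT1R libraries lay below both HPRT1 libraries on the YAC and above both when integrated. The difference of differences was -27.0 percentiles (exact permutation within sequences, two-sided, p = 0.0556, the smallest possible, n = 2 per group), which does not pass the threshold. It compares configurations with unlike baselines, since the expected pileup over the insert was higher in YAC libraries. No explanation for it was tested. No library stood apart from the rest by Dixon's test in 15 tests over groups of libraries; chance alone would give about 1 in 20.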

How the results depend on the processing

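The settings with integrated libraries alone, division by native values and recalled summits, the stricter overlap between groups, and all those of peak strength by sequence, were chosen after seeing the data. Higher peak density and coverage on the synthetic sequence than on native chromosomes kept their direction and their side of the threshold under a stricter q, equal numbers of peaks and a length of 100 kb, with differences from 1.47 to 2.25 peaks per 10 kb and from 11.4 to 13.3 percentage points. In the integrated libraries alone they were 1.29 and 2.36 over the contig and 1.9 and 6.19 over 100 kb, so that the coverage difference depends on the length, and 4 libraries cannot pass the threshold. Every row of the lists was a separate interval, so that counting rows in place of intervals moved nothing and is void. Depth may limit the weakest marks, though this was not settled here. The lists end at a −log10 q of 1.38 to 1.66. Over the insert, where YAC libraries had 5.32 times the expected pileup, regions with folds down to 1.2 were listed in these libraries alone.

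With a −log10 q of at least 5, the mean number of peaks was 3557, the share of genes marked 74.3%, and the YAC-integrated density difference 1.49 (now past the threshold). The genes separating the sequences were 1 and the glycolysis list 1.88 points above random lists, on the other side of them. With equal numbers of peaks these were 3463, 73.1%, 1.71 (past the threshold), 3 and 3.18. The interaction was 9.01e-05 on the other side of 0, and the HPRT1R share of common positions 58.1%, no longer past the threshold. Replicate overlap was 80.9% with a reciprocal overlap of 50% and 72.0% with summits within 150 bp. With summits within 500 bp after the gene start, 42.8% of genes were marked, 4 gene lists passed in place of 9 and 5 genes separated the sequences. Here 3 lists lay on the other side of random lists: ribosomal proteins at -6.06, glycolysis at 6.38 and methionine and sulfur at 2.60 points. Divided by native values, the YAC-integrated density ratio differed by 0.299 (past the threshold) and the HPRT1R-HPRT1 coverage ratio by 0.0177, on the other side of 0. The causes of these shifts were not tested. With summits recalled at the genome-wide expected pileup, the YAC-integrated density difference was 0.325.

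The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated between -0.0855 and 0.134 over 6 pairs of groups, and 1 exceeded 0.1. Permuting with the replicate block, or within the other factor, left the YAC-integrated coverage difference of 17.8 points at a permutation p of 0.0556, the smallest such a test can give; no other call changed with the block.

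Leaving out each library in turn, HPRT1R against HPRT1 density ranged from -0.49 to 0.088 and coverage from -4.21 to 2.47 points. With 1 library out, the sequences differ in their share of YAC libraries, so that the YAC-integrated difference enters these values. YAC against integrated density on the contig ranged from 0.739 to 1.27 (past the threshold without HPRT1R YAC replicate 1), and the interaction from -1.27 to 0.307. Counts ranged as follows: the genes separating the sequences from 0 to 7, those separating YAC from integrated libraries from 30 to 39, the chromosome XI stretches from 3 to 7, and the glycolysis list from -4.50 to 3.95. With fewer libraries the rules for separating genes and stretches are easier to meet, so that their counts tend to rise by construction. Over 12 settings, the galactose list lost its call in 4 and the purine list in 2, and the list of alpha-specific genes gained one in 4. The difference of differences in peak strength kept its sign, from -28.2 to -21.8 with a stricter q, equal numbers of peaks or 100 kb and from -31.1 to -22.8 with a library left out.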

Other observations

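The tests of native coverage, medium, reads over the insert, the whole effect of chromosome ends, side of the genes and peak edges, and the splits by sequence, were chosen after the result was seen.

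The expected pileup was also above the genome-wide value over some native regions. Over the tandem CUP1 genes of chromosome VIII it was 1.57 to 2.23 times the genome-wide value, and over the ribosomal DNA of chromosome XII 31.5 to 41.1 times, in all 8 libraries. Outside these arrays, MAS1 on chromosome XII had 2.01 times on average in the integrated libraries. Over mitochondrial peaks it was 1.79 to 2.55 times in YAC and about 1.00 times in integrated libraries.

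More of the insert lay under peaks in YAC than in integrated libraries. The YAC libraries had the higher genome-wide expected pileup, 88.9 ± 8.79 against 78.5 ± 3.27 reads (SD, n = 4 each; exact permutation p = 0.0571). Depth or sensitivity acting genome-wide would raise native coverage too, yet this differed by -1.76 percentage points (largest SD 0.841), which argues against it as the whole cause. The expected pileup over the insert was 5.32 times the genome-wide value in YAC libraries, so that more copies or better recovery of the YAC may bring weak peaks past the threshold. Scaled to the genome-wide expectation at their own fold, 53.5 ± 8.70 insert peaks (SD, n = 4) still passed in YAC libraries, against 50.3 on average and 52 at most in integrated ones, a margin within the spread that leaves this open; widths were not rescaled. The 2 configurations shared 0 culture media, so that medium cannot be told apart from configuration.

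The insert had more bases under peaks than native chromosomes. In the integrated libraries the expected pileup over the insert was 1.04 to 1.08 times the genome-wide value. The difference there was 6.19 percentage points, higher in 4 of 4 libraries, without an excess of reads as large as in YAC libraries. A smaller excess is not excluded: the highest ratio among insert peaks was 1.29 to 1.39 per library. The lower limit of the expected pileup also hides any lower depth on native chromosomes. Chromosome ends hold few peaks, but with the outer 20 kb left out the difference in integrated libraries was still 5.04 ± 0.440 points (SD, n = 4), which argues against the ends as the whole cause. Among inner native windows the lowest of the integrated libraries stood at percentile 87.8, short of the bound of 95 set before, so that some native stretches of this length are covered as much. A property of foreign sequence that leads to many weak peaks may be the source, which these data did not test.

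Of the genes annotated on native chromosomes, 27 were marked in one configuration alone. LEU2, of which the strain lacks the native copy, is among them. Of the 35 splits of the 8 libraries, 1 (the real one) gave as many, the highest of the others giving 14. This argues against chance for the count if the 8 libraries are independent, but cannot exclude it, 1 of 35 being the smallest share possible. The split with 14 genes followed neither configuration, sequence nor replicate number. Among the 3 splits that keep replicates together the counts were 27, 4 and 0, too few splits to decide if the libraries are not independent. For HPRT1 against HPRT1R the count was 0, which all 35 splits reach by construction, so that it decides nothing. The peaks were mostly weak, with a median percentile of 20.5, as peaks near the caller's threshold would be, though such peaks would then have to differ between configurations. Of the 27 genes, 16 lay at or below percentile 25 and 11 above it, 4 of these above percentile 50. A lower sensitivity on one side as the whole cause would put nearly all genes on the other, but 66.7% were on the integrated side; by summits 10 were, against 14 on the YAC side, and of stretches outside chromosome XI 61 of 76 were. Peak edges may account for 14.8%, CHA1 among them. Medium and configuration stay open as biological candidates, neither of them tested.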
